A study of Caenorhabditis elegans with 12 samples.

How the data were processed

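Gene expression was measured by RNA-seq of whole C. elegans at day 10 in 12 libraries, 3 biological replicates each of N2, daf-2, spr-4;spr-3 and spr-4;spr-3;daf-2. Per the labels, 100 worms per strain were grown at 20 °C, RNA was taken with Trizol and a column kit, cDNA was made with a SMART-Seq v4 kit from 2 ng of RNA because aged worms gave little, and sheared cDNA (mean 150 bp) was made into libraries and read as paired ends of 75 bp. The kit does not mark the strand or single molecules. The authors aligned reads with STAR (version not given) to WBcel235 and counted them per gene with featureCounts 1.5.1. The deposited table holds raw counts for 46739 genes, whole numbers with no normalization and a column for each library, and 0 columns of other samples. Annotation release, strand setting and the handling of reads that fit several places are not given in the sources used here.

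Library totals run from 11892808 to 46493665 counts. A count of 3, used as the floor for lower bounds, equals 0.0645 to 0.252 CPM of the raw library total, here without the TMM factor. A gene with no reads in a group is given "at least" a fold computed with 3 counts over the whole group, and with 1 to 3 counts in a group the fold is given with its counting interval. Gene symbols were found for 43720 genes, and 46484 are in Ensembl release 115, from which coordinates were taken.

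All comparisons come from a fit of edgeR 4.0.16 (R 4.3.3) to all 12 libraries with a mean per genotype. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 18342, libraries were scaled by TMM (also for the CPM given), and dispersions and the quasi-likelihood fit were robust (common biological coefficient of variation 0.291). The contrasts were daf-2 against N2, the triple mutant against daf-2, the double mutant against N2, the triple against the double mutant, the triple mutant against N2, and the interaction. The p-values of the quasi-likelihood F-test were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05 and no threshold on fold. The standard errors given beside log2 fold changes are the fold change divided by the square root of the F value.

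Gene lists were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01 between genes and adjustment over the 40 lists of a comparison. Beside it stand camera with the correlation estimated from the data, fry, the members past the threshold over all genes, and those past it when adjusted over the list alone. The lists were written from general knowledge before the data were examined and cover DAF-16 class I and class II genes, insulin signalling, yolk, synapses, ion channels, transmitters, neuropeptides, tissues, germline and sperm, cuticle, ribosome, mitochondria, stress responses, immunity, autophagy, lysosome, lipids, sugar metabolism, proteasome and the spr genes with their partners. Members with 0 counts in a group occur in 9 list results, and placing them at their bound of 3 counts moved 0 of these medians at 2 decimals.

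Named genes follow a rule fixed before the data were examined. It takes the 11 focal genes, the 6 largest rises and falls among genes with a class symbol and 2 in each direction among those with only a sequence name (adjusted p past 0.05, mean of at least 5 CPM, no overlap between the libraries of the groups), up to 4 members of each list, and genes that turned between comparisons. The rule gives 1055 gene results, of which 804 pass. The text names part of them, picked by hand after the values were seen, for known function and also because their calls hold when a library is left out. Of all 804 calls 258 (32.1%) are lost without some library, against 1 of the 204 picked outside the focal genes, so the named genes are steadier than the calls in general. The text also names icl-1 and fat-7 in daf-2 against N2, chosen after their values were seen. Of the named genes that the rule gives in any comparison, 47 of 140 overlap another gene.

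The tools were tested on simulated data with the depths and dispersions of these libraries, in which 200 genes per comparison were changed. For the pairwise comparisons edgeR recovered 72.7 to 90.9% of genes changed 4-fold, 37.3 to 58.2% of those changed 2-fold and 2.99 to 7.46% of those changed 1.5-fold, and for the interaction 51.5%, 17.9% and 0%. Of its 537 calls 41 (7.64%) were false, above the 5% aimed for. In daf-2 against N2 DESeq2 made 21.7% false calls and limma-voom with quality weights 4.65%. The limits set at first for passing this test (recovery of 80% at 4-fold, under 15% false calls) were missed by edgeR in daf-2 against N2 and in the interaction, by limma-voom (71.2% at 4-fold) and by DESeq2, and were then replaced, so the rates themselves should be used. In a simulated comparison camera found the raised list (adjusted p = 4.7e-45, 5.9e-06 with an estimated correlation) and 0 others.

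Alternatives fixed before the data were examined were DESeq2 1.42.0 with its Wald test, limma-voom with quality weights, DESeq2 size factors and upper-quartile factors in place of TMM, no filter and a filter of 10 CPM in 3 libraries, abundant gene classes left out, a fit of only the compared groups, a term for the replicate number or for the digit in the library name, a log2 fold change of 1 or more, an adjusted p under 0.01, estimated correlation and fry for lists, and leaving out each library in turn. Alternatives added after seeing the data leave out replicates 1 and 3 of the double mutant or thin all libraries to the smallest total. Nothing deposited was left out of the main results. Reads and alignments were not analysed here.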

Results

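RNA from whole Caenorhabditis elegans worms at day 10 was sequenced in 12 libraries, with 3 biological replicates for each of 4 genotypes. The genotypes are N2 (the wild type), daf-2, spr-4;spr-3 (here the double mutant) and spr-4;spr-3;daf-2 (here the triple mutant). The gene daf-2 encodes the insulin/IGF-1 receptor, whose loss lengthens life through the transcription factor DAF-16. The genes spr-3 and spr-4 encode zinc finger proteins that were found as suppressors of a presenilin mutant, sel-12, and are compared with the vertebrate neuronal repressor REST. The series is about lifespan, neural excitation and REST, so neural lists were tested in every comparison beside insulin/IGF-1 signalling. The alleles are not given in the sources used here.

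The N2 libraries hold 29990149, 33370418 and 34778946 counts in order of replicate, and the daf-2 libraries hold 28290959, 11892808 and 46493665. Those of the double mutant hold 23712797, 32899574 and 31169237, and those of the triple mutant 27576129, 40481156 and 41738783. The count table lists 46739 genes, of which 15374 have 0 counts in every library and 18342 had enough counts to be tested (16716 of these are protein-coding). Between 14727 and 18104 genes per library have at least 10 counts. Log counts correlate at 0.95 to 0.979 within genotypes and at 0.912 to 0.954 between them. The counts of replicates differ by far more than sampling noise (chi-square per degree of freedom 21.6 to 162), so no library repeats another. Vitellogenin (yolk protein) transcripts make up 5.25 ± 1.05% of the counts in N2, 2.9 ± 0.767% in daf-2, 1.84 ± 1.02% in the double mutant and 2.67 ± 0.216% in the triple mutant (mean ± SD, n = 3 each). Values below are CPM (counts scaled to the library total times its TMM factor, mean ± SD, n = 3) or log2 fold changes ± standard error. The intervals given for folds cover the spread between libraries as edgeR models it.

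The transcripts of the mutated genes remain present in every library. For spr-3 (chromosome X, 4514093 to 4516895 of WBcel235) the replicates gave 22, 24.4 and 21.2 CPM in N2, 23.5, 25.2 and 21.2 in daf-2, 30.5, 28.5 and 26 in the double mutant, and 40.9, 37.9 and 42.5 in the triple mutant. Its RNA was thus higher in the triple mutant than in daf-2 (log2 fold change 0.8 ± 0.13, edgeR adjusted p = 0.0011) and than in N2 (0.84 ± 0.13, edgeR adjusted p = 0.00025). The rise from N2 to the double mutant did not pass (0.33 ± 0.13, edgeR adjusted p = 0.12). For spr-4 (chromosome I, 8103596 to 8109228) the values were 46.1, 76.8 and 53.8 CPM in N2, 57.8, 44.5 and 49.2 in daf-2, 39.4, 36.4 and 41.2 in the double mutant, and 36, 21.8 and 40.3 in the triple mutant. With all libraries and edgeR it passed only between the triple mutant and N2 (log2 fold change -0.85 ± 0.21, edgeR adjusted p = 0.0084, and 0.052 without replicate 2 of N2). With DESeq2 it also passes in the triple mutant against daf-2 and in the double mutant against N2 (log2 fold change -0.62 and -0.63, adjusted p = 0.043 in both). With edgeR it passes in the former without replicate 2 of N2 (adjusted p = 0.039) or replicate 3 of the triple mutant (0.042), and in the latter without replicate 2 of the triple mutant (0.036). The alleles are not known here, so transcript amounts of spr-3 and spr-4 say nothing on whether the proteins are made.

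The insulin/IGF-1 receptor gene daf-2 (chromosome III, 2994514 to 3040846) had more transcript in both daf-2 strains. The replicates gave 35, 38.7 and 36.9 CPM in N2, 62.7, 68.1 and 72.6 in the daf-2 mutant, 58.2, 45.5 and 45.8 in the double mutant, and 66.3, 56.4 and 70.8 in the triple mutant. Against N2 it rose in the daf-2 mutant (0.88 ± 0.14, edgeR adjusted p = 0.00023) and in the triple mutant (0.81 ± 0.14, edgeR adjusted p = 0.00045). The smaller rise in the double mutant is just past the threshold (0.43 ± 0.14, edgeR adjusted p = 0.049, and 0.25 without replicate 1 of the double mutant). The presenilin gene hop-1 (chromosome I, 4208515 to 4210341), whose repression by SPR proteins is known from presenilin mutants, was not significantly higher in the double mutant than in N2 (0.43 ± 0.17, edgeR adjusted p = 0.11) nor in the triple mutant than in daf-2 (0.53 ± 0.17, edgeR adjusted p = 0.05 after rounding). The latter passes with DESeq2 size factors (edgeR adjusted p = 0.048), with DESeq2 (adjusted p = 0.022) and without replicate 1 of daf-2 (0.048) or replicate 2 of the double mutant (0.044). It was lower in each daf-2 strain than in the matching strain with daf-2 intact (-0.64 ± 0.17 and -0.54 ± 0.17, edgeR adjusted p = 0.015 and 0.043, and 0.053 and 0.15 without replicate 3 of daf-2 and of the double mutant). The presenilin gene sel-12 and the genes spr-1, spr-2 and spr-5 passed in no comparison by edgeR with all libraries. With DESeq2 spr-2 passes in the triple against the double mutant (-0.32, adjusted p = 0.033). Without replicate 2 of N2, spr-1 passes in the triple mutant against N2 (edgeR adjusted p = 0.0076) and in daf-2 against N2 (0.032). Without replicate 2 of the double mutant spr-2 passes in the triple against the double mutant (edgeR adjusted p = 0.028) and in the double mutant against N2 (0.043). Of the 16 measured members of the list of spr, CoREST and presenilin genes, 2 rose and 0 fell in the double mutant (7 and 2 adjusted over the list alone, camera adjusted p = 0.078).

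**Figure D1:**
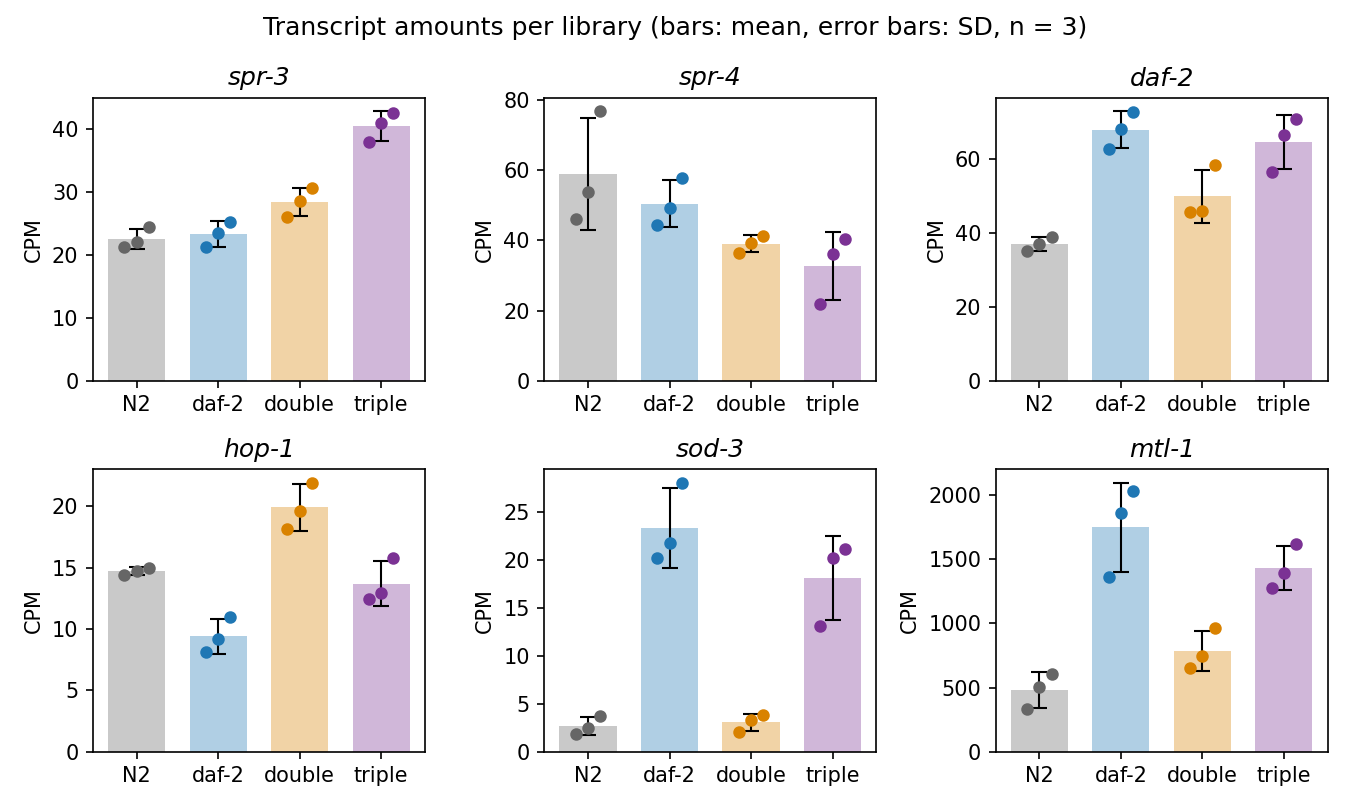
Transcript amounts in CPM (vertical axes) of spr-3, spr-4, daf-2, hop-1, sod-3 and mtl-1 in the 4 genotypes, with a point per library, bars for the mean and error bars for the SD (n = 3). The 3 libraries of the triple mutant have the highest spr-3 values, and sod-3 and mtl-1 are high in both daf-2 strains.

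Reduced insulin/IGF-1 signalling alone, the daf-2 mutant against N2, raised stress defence genes long known as targets of DAF-16. It lowered genes of the intestine, of innate immunity and of oocytes. Of these lists only intestine markers pass with an estimated correlation between genes (camera adjusted p = 0.01, against adjusted p = 0.68 and 0.77 for innate immunity and oocyte markers, all with an estimated correlation). The superoxide dismutase gene sod-3, a standard reporter of DAF-16 activity, went from 2.7 ± 0.938 to 23.3 ± 4.16 CPM (8.57-fold, interval 5.77 to 12.8). The metallothionein gene mtl-1 rose by a log2 fold change of 1.86 ± 0.22 (edgeR adjusted p = 1.7e-05). The transcript of daf-16 itself was a little higher (0.5 ± 0.13, edgeR adjusted p = 0.01, but 0.053 without replicate 1 of N2 and 0.071 without replicate 2 of daf-2). The small heat shock protein genes hsp-12.3 (2.21 ± 0.19) and hsp-12.6 (2.38 ± 0.24) and the superoxide dismutase gene sod-5 (2.3 ± 0.24) rose as well. The 3 class I targets that fell, named after their values were seen, are icl-1 (-1.08 ± 0.23), fat-7 (-1.95 ± 0.47) and the small heat shock protein gene hsp-16.41 (-1.76 ± 0.45, edgeR adjusted p = 0.02, but 0.062, 0.07 and 0.068 without replicate 3 of N2 and replicates 1 and 2 of daf-2). The glutathione S-transferase gene gst-10 (2.56 ± 0.28), the cytochrome P450 gene cyp-34A9 (2.18 ± 0.18) and the lysosomal lipase gene lipl-4 (2.65 ± 0.18) rose too. Among the largest changes, icmt-1 went from 10.2 ± 3.75 to 456 ± 37.8 CPM and the aldehyde dehydrogenase gene alh-2 from 0.414 ± 0.227 to 19.7 ± 8.21. The gene dao-6, named for expression in dauer larvae and aging adults, went from 43.5 ± 15.9 to 1270 ± 353, and the cuticle collagen gene col-50 from 3.85 ± 1.93 to 105 ± 5.79. Not a single read of clx-1 was counted in N2, against 108 ± 24.1 CPM in daf-2, a rise of at least 3250-fold.

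The lysozyme genes lys-3 (461 ± 117 to 8.73 ± 2.49 CPM) and ilys-2 (91.9 ± 15.2 to 5.06 ± 1.06) were among the innate immune genes that fell. The flavin monooxygenase gene fmo-2 (-2.88 ± 0.14) and the bZIP factor gene zip-10 (-1.86 ± 0.17) fell too. In the intestine the microvillar actin gene act-5 (-2.78 ± 0.18), the intermediate filament genes ifb-2 (-2.77 ± 0.22) and ifd-2 (-2.75 ± 0.26) and the metallothionein gene mtl-2 (-2.53 ± 0.31) fell. Falls also met the DAF-16 repressed gene dod-19 (-2.86 ± 0.23), the aspartic protease gene asp-1 (-4.02 ± 0.46) and the insulin gene ins-7 (-4.78 ± 0.42), which acts as an agonist of DAF-2. Of the genes used in oocytes, the yolk receptor gene rme-2 (-1.44 ± 0.15), the translational regulator gene puf-5 (-1.63 ± 0.16), the nanos relative nos-2 (-1.27 ± 0.14) and the polarity gene mex-5 (-1.05 ± 0.15) fell. Within the receptor pathway itself the kinase gene akt-2 (0.92 ± 0.13) and the receptor substrate gene ist-1 (1.17 ± 0.26) rose, and the kinase gene sgk-1 (-1.56 ± 0.22) fell. Of the yolk protein genes only vit-5 passed (30300 ± 6880 to 10300 ± 2620 CPM, edgeR adjusted p = 0.0061).

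No neural list passed in daf-2 against N2, though single genes did. Higher in daf-2 were the metabotropic glutamate receptor gene mgl-1 (2.79 ± 0.38), the acetylcholine receptor gene unc-38 (1.33 ± 0.17), the synaptotagmin gene snt-1 (1.13 ± 0.22), the neuropeptide gene flp-6 (1.47 ± 0.21) and the ciliary kinesin gene osm-3 (2.26 ± 0.27). The serotonin receptor gene ser-7 was lower (-1.68 ± 0.27). Of 30 synaptic vesicle release genes 4 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.44). Of 33 ion channel genes 1 rose and 4 fell (1 and 3 over the list alone, camera adjusted p = 0.95). The lists for glutamate (3 up, 1 down of 28), acetylcholine (1 and 5 of 42), GABA (0 and 1 of 14) and monoamine signalling (1 and 1 of 27), FMRFamide-like peptides (1 and 0 of 30), neuropeptide-like proteins (3 and 6 of 56) and pan-neuronal markers (1 and 4 of 24) did not pass either (camera adjusted p = 0.73, 0.76, 0.77, 0.7, 0.44, 0.75 and 0.72). Of 35 insulin-like peptide genes 7 rose and 9 fell (camera adjusted p = 0.94). Of all tested genes 20.6% changed, and whether neural genes differ from this share was not tested.

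Over all tested genes edgeR called 1757 higher and 2015 lower in daf-2 than in N2 (20.6%), and 887 and 925 of these changed at least 2-fold. Lists have the camera adjusted p at a preset correlation between genes, then that at an estimated one. Every value of a genotype lay beyond every value of the other for 39.9% of the tested genes, where chance gives 10%. DAF-16 class I targets, genes reported higher in daf-2 mutants, rose as a list (16 up, 3 down of 27, and 17 and 4 over the list alone, camera adjusted p = 2e-05, adjusted p = 0.22 with an estimated correlation). Class II genes, reported lower, fell (0 up, 5 down of 9, the same over the list alone, camera adjusted p = 0.00067, adjusted p = 0.068 with an estimated correlation). Intestine markers fell under both forms of the test (0 up, 13 down of 23, and 1 and 14 over the list alone, camera 1.9e-08, adjusted p = 0.01 with an estimated correlation). The other calls do not survive the estimate. Innate immune genes (3 up, 21 down of 39, 4 and 22 over the list alone) fell with camera adjusted p = 8.4e-08 (adjusted p = 0.68 with an estimated correlation). Oocyte and early embryo markers (5 up, 19 down of 40, 8 and 19 over the list alone) fell with camera adjusted p = 0.00067 (adjusted p = 0.77 with an estimated correlation). Detoxification genes associated with SKN-1 rose (10 up, 4 down of 34, 12 and 5 over the list alone, camera adjusted p = 0.038, adjusted p = 0.77 with an estimated correlation). So did the 12 genes of mitochondrial DNA (5 up, 0 down, 6 and 0 over the list alone, camera adjusted p = 0.0018, adjusted p = 0.77 with an estimated correlation). Proteasome genes fell a little (0 up, 5 down of 31, 0 and 3 over the list alone, median log2 fold change -0.17, camera adjusted p = 0.049, adjusted p = 0.92 with an estimated correlation). The call for proteasome genes is lost without replicate 1 or 2 of N2 or 2 of daf-2 (camera adjusted p = 0.063, 0.18 and 0.056), and that for detoxification genes without replicate 2 of N2 or 1 of daf-2 (0.057 and 0.085). By fry the proteasome is not called (adjusted p = 0.2).

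**Figure D2:**
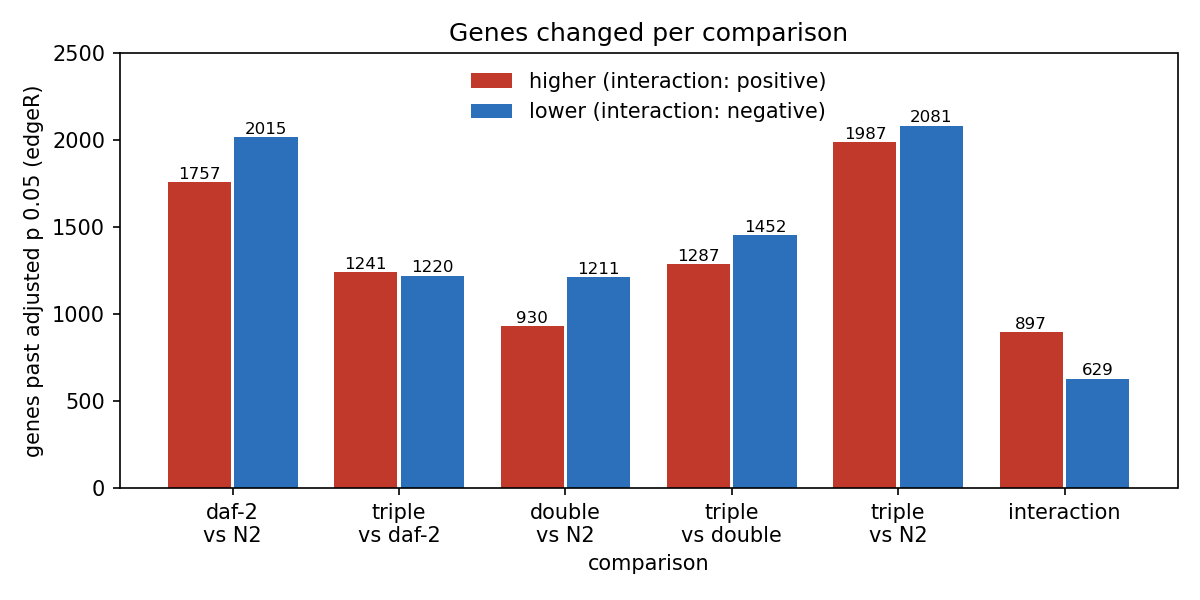
Bars give the number of genes past an adjusted p of 0.05 by edgeR (vertical axis), higher in red and lower in blue, for each of the 5 comparisons and the interaction. The triple mutant against N2 has the most calls, 1987 higher and 2081 lower.

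Loss of spr-3 and spr-4 in the daf-2 background, the triple mutant against daf-2, raised cuticle collagen genes, genes of cilia and oocyte genes, and lowered genes of lysosomes, lipid metabolism and the insulin/IGF-1 pathway. With an estimated correlation 0 of the 10 lists called here pass (camera adjusted p = 0.19 to 0.67). Many of the changes ran against those seen in daf-2 against N2, a comparison that uses the same daf-2 libraries. Several oocyte genes that were lower in daf-2 than in N2 were higher here. The yolk receptor gene rme-2 went from 485 ± 29.4 to 1170 ± 153 CPM (N2 1320 ± 120). The log2 fold change was 0.88 ± 0.13 for nos-2 and 0.79 ± 0.15 for the eggshell gene egg-1 and 0.69 ± 0.14 for the oocyte maturation gene oma-1. The collagen genes col-81 (3.48 ± 0.28), col-2 (3.43 ± 0.27) and col-71 (2.72 ± 0.21) rose from low levels. So did the kinase gene mapk-15 (3.65 ± 0.31), the prolyl isomerase gene fkb-4 (2.96 ± 0.19) and the pharyngeal cuticle gene abu-14 (2.93 ± 0.23). W01B6.6 went from 0.396 ± 0.175 to 20.1 ± 2.33 CPM and its neighbour W01B6.5 from 0.412 ± 0.358 to 21.6 ± 4.43. The moulting protease gene nas-37 (24.4 ± 2.57 to 2.82 ± 1.04 CPM), nspa-8 (-2.82 ± 0.32), the G protein gene gpa-10 (-2.4 ± 0.38) and the tyrosinase gene tyr-3 (-2.38 ± 0.36) fell.

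Some genes of fat and lysosomal metabolism were lower in the triple mutant than in daf-2. Neither list passes with an estimated correlation. Of the genes named fat-6, lipl-4, vha-3, ftn-1 and cyp-35B1 had passed as higher in daf-2 than in N2, but not fat-5, cpl-1, vha-12 and lys-7. The stearoyl-CoA desaturase genes fat-6 (295 ± 6.1 to 117 ± 13.7 CPM, against 140 ± 16.6 in N2) and fat-5 (-0.96 ± 0.17) fell, as did lipl-4 (-1.17 ± 0.17). The acyl-CoA dehydrogenase gene acdh-1 rose (1.82 ± 0.24). The cathepsin L gene cpl-1 (-0.75 ± 0.15) and the V-ATPase subunit genes vha-12 (-0.62 ± 0.13) and vha-3 (-0.83 ± 0.18) fell. So did the ferritin gene ftn-1 (-0.95 ± 0.18), the cytochrome P450 gene cyp-35B1 (-0.81 ± 0.16) and the lysozyme gene lys-7 (-1.12 ± 0.23). In the insulin/IGF-1 pathway ist-1 (-1.34 ± 0.26), akt-2 (-0.62 ± 0.13) and the transcription factor gene pqm-1 (-0.77 ± 0.17) fell. The autophagy gene epg-2 fell too (-1.16 ± 0.21). The gene fmo-2 rose from 11.2 ± 0.98 to 29.8 ± 0.99 CPM, part of the way to the 82.6 ± 3.52 of N2. The intermediate filament gene ifas-1 rose by 2.1 ± 0.27. The class I targets sod-3 (-0.36 ± 0.26, edgeR adjusted p = 0.42) and mtl-1 (-0.29 ± 0.21, edgeR adjusted p = 0.42) did not change past the threshold.

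Neural genes moved in both directions. The Munc18 gene unc-18 (-0.6 ± 0.12), the SNAP-25 gene ric-4 (-1.03 ± 0.21) and the proprotein convertase gene egl-3 (-0.63 ± 0.15), all needed for release of transmitters or peptides, fell. So did the glutamate-gated chloride channel gene glc-1 (-1.21 ± 0.14), the octopamine synthesis gene tbh-1 (-0.94 ± 0.14), the GTP cyclohydrolase gene cat-4 (-0.75 ± 0.15), which serves dopamine and serotonin synthesis, and flp-6 (-1.38 ± 0.21). Rises met the NMDA receptor subunit gene nmr-2 (1.36 ± 0.29), the acetylcholine receptor gene acr-20 (2.13 ± 0.28), the GABA receptor gene unc-49 (0.7 ± 0.16) and the ciliary genes gcy-35 (1.81 ± 0.27), ift-74 (2.11 ± 0.36), dyf-2 (1.19 ± 0.22) and dyf-7 (1.24 ± 0.28). The insulin genes ins-5 (2.24 ± 0.32) and ins-3 (1.29 ± 0.27) rose. Of 30 synaptic vesicle release genes 0 rose and 3 fell (the same over the list alone, camera adjusted p = 0.37). Glutamate signalling (2 up, 1 down of 28), acetylcholine signalling (3 up, 0 down of 42) and monoamine signalling (0 up, 2 down of 27) did not pass as lists (camera adjusted p = 0.47, 0.37 and 0.76).

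In this comparison edgeR called 1241 genes higher and 1220 lower (13.4% of those tested), 579 and 501 of them by at least 2-fold. Of all tested genes 36% did not overlap between the genotypes (10% by chance). Oocyte and early embryo markers rose (16 up, 0 down of 40, 19 and 0 over the list alone, camera adjusted p = 3.1e-07, adjusted p = 0.54 with an estimated correlation). Collagens rose (12 up, 3 down of 123, 12 and 2 over the list alone, camera adjusted p = 0.00088, adjusted p = 0.61 with an estimated correlation), and so did ciliated neuron genes (6 up, 0 down of 47, the same over the list alone, camera adjusted p = 0.004, adjusted p = 0.19 with an estimated correlation). Lipid metabolism (2 up, 11 down of 47, 2 and 14 over the list alone) fell with camera adjusted p = 0.00028 (adjusted p = 0.19 with an estimated correlation), and the lysosome and V-ATPase list (0 up, 12 down of 37, 0 and 14 over the list alone) with 0.00052 (adjusted p = 0.26 with an estimated correlation). Class I targets (1 up, 8 down of 27, 2 and 8 over the list alone, camera adjusted p = 0.018, adjusted p = 0.61 with an estimated correlation) and the insulin/IGF-1 pathway (0 up, 4 down of 18, the same over the list alone, camera adjusted p = 0.04, adjusted p = 0.54 with an estimated correlation) fell. Autophagy genes (0 up, 3 down of 27, the same over the list alone) fell with camera adjusted p = 0.04 (adjusted p = 0.61 with an estimated correlation). The genes of mitochondrial DNA (0 up, 3 down of 12, 0 and 7 over the list alone) fell with camera adjusted p = 0.0013 (adjusted p = 0.67 with an estimated correlation). Major sperm protein genes fell too (0 up, 7 down of 25, the same over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.61 with an estimated correlation), though these near-identical genes make up only 0.00147 ± 0.000123% of the counts in the triple mutant. Without replicate 2 of daf-2 or of the triple mutant the insulin/IGF-1 pathway (camera adjusted p = 0.097 and 0.085) and autophagy (0.11 and 0.085) lose their calls. Collagens and genes of mitochondrial DNA are not called by fry (adjusted p = 0.094 in both). The total count falls to 1568, 1376 and 1525 genes without replicate 2 of daf-2, replicate 3 of daf-2 and replicate 3 of the triple mutant, while limma-voom with quality weights calls 3977.

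With daf-2 intact, loss of spr-3 and spr-4 (the double mutant against N2) lowered yolk protein, innate immune, intestinal and lysosomal genes and raised genes of the cuticle, of oocytes and of embryonic patterning. With an estimated correlation 0 of the 11 lists called here pass (camera adjusted p = 0.14 to 0.86). All 3 rises are also lost without replicate 3 of N2 (camera adjusted p = 0.088 for the cuticle, 0.18 for oocytes and 0.14 for patterning). The yolk gene vit-5 went from 30300 ± 6880 to 7490 ± 4890 CPM (4.03-fold lower, interval 2.49 to 6.54) and vit-6 from 9760 ± 1990 to 2830 ± 1860. The cathepsin B-like gene cpr-5 fell from 1430 ± 207 to 170 ± 66.7 CPM and the lipase gene lipl-8 from 14.2 ± 2.27 to 0.324 ± 0.281. The lysozyme genes ilys-2 (-3.22 ± 0.23) and lys-3 (-1.85 ± 0.22) and fmo-2 (-1.26 ± 0.13) were lower as well. The intestinal GATA factor gene elt-7 (-1.05 ± 0.16) fell with act-5 (-0.86 ± 0.17), the lysosomal DNase gene nuc-1 (-1.59 ± 0.22), dod-19 (-1.35 ± 0.22) and the epidermal antimicrobial peptide genes nlp-33 (-2.15 ± 0.3) and nlp-30 (-1.46 ± 0.23). The gene fipr-23, of a related family, was higher (2.38 ± 0.31).

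Several genes that rose from near silence were the same as in the daf-2 background. W01B6.6 went from 0.216 ± 0.126 to 13.9 ± 2.6 CPM, W01B6.5 from 0.231 ± 0.281 to 11.9 ± 2.09, the tau tubulin kinase relative ttbk-4 from 0.956 ± 0.488 to 19.2 ± 3.33. The gene mapk-15 went from 1.42 ± 0.399 to 16.3 ± 5.13, tag-344 from 1.68 ± 0.961 to 15.3 ± 1.95 and col-2 from 2.2 ± 0.811 to 19.1 ± 2.27. The growth factor gene svh-1 (2.95 ± 0.45), the acyl-CoA synthetase gene acs-6 (2.93 ± 0.4), acdh-1 (2.78 ± 0.26), the lactate dehydrogenase gene ldh-1 (0.86 ± 0.13) and the cuticle collagen gene dpy-9 (2.6 ± 0.3) also rose. Of oocyte and embryo genes, cey-2 (0.84 ± 0.14), the eggshell genes egg-2 (1.11 ± 0.19) and egg-3 (0.93 ± 0.18), the meiotic gene htp-1 (0.94 ± 0.16), the endoderm GATA factor gene end-3 (2.21 ± 0.37) and the Notch receptor gene lin-12 (0.93 ± 0.2) were higher. In neurons and their partners the neurexin gene nrx-1 (1.59 ± 0.24) and the acetylcholine receptor genes acr-20 (1.84 ± 0.28) and acr-16 (1.63 ± 0.35) rose. In contrast glc-1 (-0.66 ± 0.14), the glutamate transporter gene glt-3 (-0.87 ± 0.17), the dense core vesicle gene ida-1 (-0.64 ± 0.14) and nlp-56 (-1.3 ± 0.26) fell.

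The edgeR test called 930 genes higher and 1211 lower (11.7%), with 388 and 474 changed at least 2-fold. A fit of these 2 genotypes alone called 983, 402 higher and 581 lower. Of the tested genes 28.5% did not overlap (10% by chance). Vitellogenins fell (0 up, 4 down of 6, 0 and 6 over the list alone, camera adjusted p = 3.9e-07, adjusted p = 0.42 with an estimated correlation). So did innate immune genes (3 up, 12 down of 39, 4 and 18 over the list alone, camera adjusted p = 4.6e-08, adjusted p = 0.45 with an estimated correlation). Intestine markers (0 up, 5 down of 23, the same over the list alone) fell with camera adjusted p = 0.00037 (adjusted p = 0.14 with an estimated correlation). Class II genes (0 up, 3 down of 9, the same over the list alone) followed with camera adjusted p = 0.014 (adjusted p = 0.2 with an estimated correlation). Lysosomal genes (0 up, 4 down of 37, the same over the list alone) and epidermal antimicrobial peptides (4 up, 6 down of 25, 4 and 10 over the list alone) both fell with camera adjusted p = 0.035 (adjusted p = 0.49 and 0.86 with an estimated correlation). Insulin-like peptides fell (0 up, 5 down of 35, the same over the list alone, camera adjusted p = 0.028, adjusted p = 0.76 with an estimated correlation). Major sperm protein genes fell (0 up, 6 down of 25, 0 and 18 over the list alone, camera adjusted p = 4.6e-08, adjusted p = 0.49 with an estimated correlation). Oocyte markers (7 up, 3 down of 40, 12 and 3 over the list alone) and embryonic patterning genes (3 up, 0 down of 28, the same over the list alone) rose with camera adjusted p = 0.01 (adjusted p = 0.67 and 0.45 with an estimated correlation), and moulting and cuticle genes (5 up, 1 down of 30, 9 and 1 over the list alone) with 0.028 (adjusted p = 0.2 with an estimated correlation). Synaptic vesicle release (3 up, 2 down of 30), glutamate (2 and 2 of 28), acetylcholine (3 and 1 of 42) and monoamine genes (4 and 1 of 27) did not pass as lists (camera adjusted p = 0.39, 0.98, 0.36 and 0.28). Other calls lost without a library are insulin-like peptides (camera adjusted p = 0.13, 0.1 and 0.061 without replicates 1 and 3 of N2 and 3 of the double mutant), antimicrobial peptides (0.43 and 0.061 without replicate 3 of N2 and 2 of the double mutant), lysosomal genes (0.11 and 0.061 without replicate 2 of N2 and of the double mutant) and moulting genes (0.066 without replicate 2 of the double mutant). Insulin-like peptides, oocyte markers and antimicrobial peptides are not called by fry (adjusted p = 0.25, 0.097 and 0.42). Replicate 2 of the double mutant held more vitellogenin RNA (3% of its counts) than replicates 1 and 3 (1.08% and 1.45%). Without it 3139 genes pass, and the count falls to 1048, 1011, 1030 and 943 genes without replicate 1 or 3 of N2 or replicate 1 or 3 of the double mutant.

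Where spr-3 and spr-4 were missing, the daf-2 mutation (the triple mutant against the double mutant) again raised stress defence genes and lowered intestinal and immune genes. Yolk protein and muscle lists were higher as well. With an estimated correlation only the fall of intestine markers passes among the 18 lists called. The effect of daf-2 on the muscle list was not shown to depend on spr-3 and spr-4 (interaction, camera adjusted p = 0.56). The genes icmt-1 (4.4 ± 0.23), alh-2 (5.96 ± 0.43), col-50 (3.04 ± 0.28), sod-3 (3.08 ± 0.885 to 18.1 ± 4.37 CPM), sod-5 (2.51 ± 0.24), hsp-12.3 (1.89 ± 0.18), lipl-4 (1.44 ± 0.17), mgl-1 (2.06 ± 0.38) and unc-38 (1.46 ± 0.17) rose in this background too. The small heat shock protein gene sip-1 rose by 1.29 ± 0.19. Of the falling genes, lys-3 (-3.02 ± 0.24), ilys-2 (-2.21 ± 0.24), ins-7 (-3.61 ± 0.4), dod-19 (-1.7 ± 0.22), act-5 (-1.75 ± 0.18), ifb-2 (-1.56 ± 0.21) and ifd-2 (-2.56 ± 0.26) repeat the pattern with spr-3 and spr-4 intact. The aspartic protease gene asp-17 (82.7 ± 46.9 to 3.13 ± 1.35 CPM) and the cathepsin B-like gene cpr-2 (161 ± 128 to 3.97 ± 1.43) fell too. The endoplasmic reticulum chaperone genes hsp-3 (-1.32 ± 0.16), hsp-4 (-1.2 ± 0.2) and crt-1 (-1.13 ± 0.16), the autophagy gene lgg-2 (-0.68 ± 0.14), cpl-1 (-1.05 ± 0.15) and vha-12 (-0.79 ± 0.13) fell. Muscle genes were higher, such as the paramyosin gene unc-15 (469 ± 114 to 1010 ± 38.2 CPM) and the actin gene act-4 (1.2 ± 0.23). So were glt-3 (1.48 ± 0.17) and the ciliary genes arl-13 (1.91 ± 0.22) and dyf-7 (1.58 ± 0.28).

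Here 1287 genes were higher and 1452 lower by edgeR (14.9%), 654 and 503 at least 2-fold, with 30.7% of tested genes not overlapping (10% by chance). Only the fall of intestine markers passed both forms of the test (0 up, 11 down of 23, 0 and 14 over the list alone, camera 5.4e-08, adjusted p = 0.013 with an estimated correlation). Class I targets rose (10 up, 2 down of 27, 10 and 3 over the list alone, camera adjusted p = 0.00069, adjusted p = 0.22 with an estimated correlation). Class II genes fell (0 up, 3 down of 9, 0 and 5 over the list alone, camera adjusted p = 0.012, adjusted p = 0.21 with an estimated correlation). Vitellogenins rose (2 up, 0 down of 6, 4 and 0 over the list alone, camera adjusted p = 0.0017, adjusted p = 0.47 with an estimated correlation). Muscle markers (8 up, 4 down of 30, 12 and 5 over the list alone) rose with camera adjusted p = 0.044 (adjusted p = 0.22 with an estimated correlation). The cytosolic heat shock list (5 up, 0 down of 19, 6 and 0 over the list alone) rose with camera adjusted p = 0.017 (adjusted p = 0.57 with an estimated correlation). Ribosomal protein genes (4 up, 0 down of 81, 3 and 0 over the list alone) rose by a median of only 0.2 (camera adjusted p = 0.0046, adjusted p = 0.82 with an estimated correlation). Other sperm genes (4 up, 2 down of 25, 6 and 2 over the list alone) rose with camera adjusted p = 0.016 (adjusted p = 0.26 with an estimated correlation). Major sperm protein genes shifted up without a call for any of the 25 genes (camera adjusted p = 0.046, adjusted p = 0.78 with an estimated correlation). Collagens (19 up, 3 down of 123, 21 and 3 over the list alone) and ciliated neuron genes (6 up, 1 down of 47, the same over the list alone) rose with camera adjusted p = 0.005 and 0.034 (adjusted p = 0.56 and 0.22 with an estimated correlation). Lists that fell were lysosome (2 up, 10 down of 37), autophagy (0 up, 6 down of 27), the unfolded protein response (0 up, 7 down of 23), innate immunity (3 up, 11 down of 39), proteasome (1 up, 6 down of 31), oocyte markers (3 up, 8 down of 40) and lipid metabolism (5 up, 13 down of 47). Their camera adjusted p were 0.00041, 0.0019, 0.0046, 0.0046, 0.0046, 0.017 and 0.048 (in the same order adjusted p = 0.21, 0.22, 0.43, 0.57, 0.6, 0.6 and 0.36 with an estimated correlation). The yolk result rests on replicates 1 and 3 of the double mutant, since its replicate 2 holds 3% vitellogenin counts and the triple mutant libraries 2.42 to 2.82%, and without replicates 1 and 3 the list does not pass (camera adjusted p = 0.44, an alternative added after seeing the data). Other lists are lost with them, among them the proteasome (0.65), other sperm genes (0.3) and collagens (0.094). Calls lost without a single library of the triple mutant are ciliated neuron genes (0.13, replicate 3), muscle (0.057 and 0.087, replicates 1 and 2), oocyte markers (0.073, replicate 2), major sperm proteins (0.087, replicate 3), ribosomal proteins (0.61, replicate 2), heat shock (0.099, replicate 1) and lipid metabolism (0.057 and 0.056, replicates 2 and 3), all camera adjusted p. Without a library of the double mutant the camera adjusted p is 0.45 for major sperm proteins and 0.079 for the proteasome (replicate 3), 0.062 for innate immunity (replicate 2) and 0.067 and 0.066 for lipid metabolism (replicates 1 and 3), and without replicate 2 of daf-2 the last is at 0.05. With DESeq2 size factors major sperm proteins and lipid metabolism lose their calls (camera adjusted p = 0.05 after rounding and 0.052). Vitellogenins, oocyte markers, major sperm and ribosomal proteins, heat shock, innate immunity and the proteasome are not called by fry (adjusted p = 0.053, 0.093, 0.26, 0.4, 0.083, 0.12 and 0.069). Synaptic vesicle release (2 up, 3 down of 30), glutamate (4 and 3 of 28), acetylcholine (2 and 0 of 42), monoamine (1 and 3 of 27) and pan-neuronal genes (2 and 4 of 24) did not pass (camera adjusted p = 0.27, 0.86, 0.74, 0.31 and 0.27), but the last 2 fell by fry (adjusted p = 0.04 in both). The total falls to 1582 without replicate 3 of the double mutant and to 1693 without replicate 3 of the triple mutant.

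The triple mutant against N2 keeps part of both sets of changes. The lysozyme gene ilys-2 fell from 91.9 ± 15.2 to 2.09 ± 0.671 CPM and lys-3 from 461 ± 117 to 15.7 ± 3.55. The sodium/proton exchanger gene nhx-6 went from 10.6 ± 1.67 to 0.021 ± 0.0189, where so few reads remain that counting alone leaves a fold between 156 and 4670. The cathepsin B-like gene cpr-8 (-6.46 ± 0.59), asp-1 (-3.85 ± 0.45), nuc-1 (-2.23 ± 0.22), cpl-1 (-1.07 ± 0.15), dod-19 (-3.05 ± 0.23), act-5 (-2.6 ± 0.18), ifd-2 (-2.97 ± 0.26) and ifb-2 (-2.02 ± 0.21) fell. So did the chaperone gene hsp-3 (-1.39 ± 0.16). Rises of icmt-1 (5.58 ± 0.24), alh-2 (5.05 ± 0.4), sod-3 (2.74 ± 0.29), mtl-1 (1.57 ± 0.22), sod-5 (2.91 ± 0.24) and hsp-12.3 (2.06 ± 0.18) carry the daf-2 pattern. Those of mapk-15 (4.42 ± 0.33), ttbk-4 (4.33 ± 0.33), col-2 (3.93 ± 0.27) and acdh-1 (3.32 ± 0.26) carry that of spr-3 and spr-4. The receptor genes acr-20 (2.85 ± 0.28) and unc-38 (1.86 ± 0.17) and the glutamate receptor partner sol-2 (1.98 ± 0.26) were higher too. This pair had the most edgeR calls, 1987 higher and 2081 lower (22.2%, 1080 and 1015 at least 2-fold, 38.9% not overlapping against 10% by chance).

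Of the lists in the triple mutant against N2, the falls of intestine markers (0 up, 17 down of 23, the same over the list alone, camera 1.8e-12, adjusted p = 0.0028 with an estimated correlation), lysosomal genes (0 up, 14 down of 37, 0 and 16 over the list alone, 1.9e-07 and 0.046) and class II genes (0 up, 5 down of 9, the same over the list alone, 0.00065 and 0.046) passed both forms of the test. Innate immune genes (4 up, 23 down of 39, 5 and 26 over the list alone) fell with camera adjusted p = 4.1e-09 (adjusted p = 0.34 with an estimated correlation). Lipid metabolism (5 up, 18 down of 47, 6 and 22 over the list alone) fell with camera adjusted p = 0.0068 (adjusted p = 0.18 with an estimated correlation). Major sperm protein (0 up, 3 down of 25), unfolded protein response (2 up, 10 down of 23), epidermal antimicrobial (4 up, 9 down of 25) and autophagy genes (0 up, 4 down of 27) fell with camera adjusted p = 0.0025, 0.029, 0.025 and 0.044 (adjusted p = 0.69, 0.59, 0.88 and 0.59 with an estimated correlation). Collagens (26 up, 9 down of 123), ciliated neuron genes (9 up, 0 down of 47), class I targets (10 up, 3 down of 27) and embryonic patterning genes (3 up, 1 down of 28) rose with camera adjusted p = 0.0025, 0.013, 0.029 and 0.031 (adjusted p = 0.59, 0.17, 0.59 and 0.59 with an estimated correlation). Calls lost without a library are class I targets (camera adjusted p = 0.053, replicate 1 of N2), embryonic patterning (0.19 and 0.052, replicate 3 of N2 and 2 of the triple mutant), the unfolded protein response (0.075, replicate 2 of N2), antimicrobial genes (0.16 and 0.071, replicate 3 of N2 and of the triple mutant) and autophagy (0.15, 0.053 and 0.091, replicates 2 and 3 of N2 and 2 of the triple mutant). Major sperm proteins and antimicrobial genes are not called by fry (adjusted p = 0.063 and 0.23). Synaptic vesicle release (4 up, 2 down of 30), glutamate (5 and 4 of 28), acetylcholine (2 and 4 of 42), monoamine (2 and 3 of 27) and pan-neuronal genes (2 and 3 of 24) did not pass (camera adjusted p = 0.85, 0.77, 0.77, 0.79 and 0.34), but the last fell by fry (adjusted p = 0.02). The lists of pharynx, hypodermis and coelomocyte, glia and excretory markers, of the nuclear-encoded respiratory chain and of glycolysis, glyoxylate and trehalose genes passed in no comparison by camera with all libraries. In this pair their camera adjusted p were 0.34, 0.77, 0.7, 0.77 and 0.34. By fry the coelomocyte, glia and excretory list fell here and in the double mutant against N2 (adjusted p = 0.02 and 0.026).

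**Figure D3:**
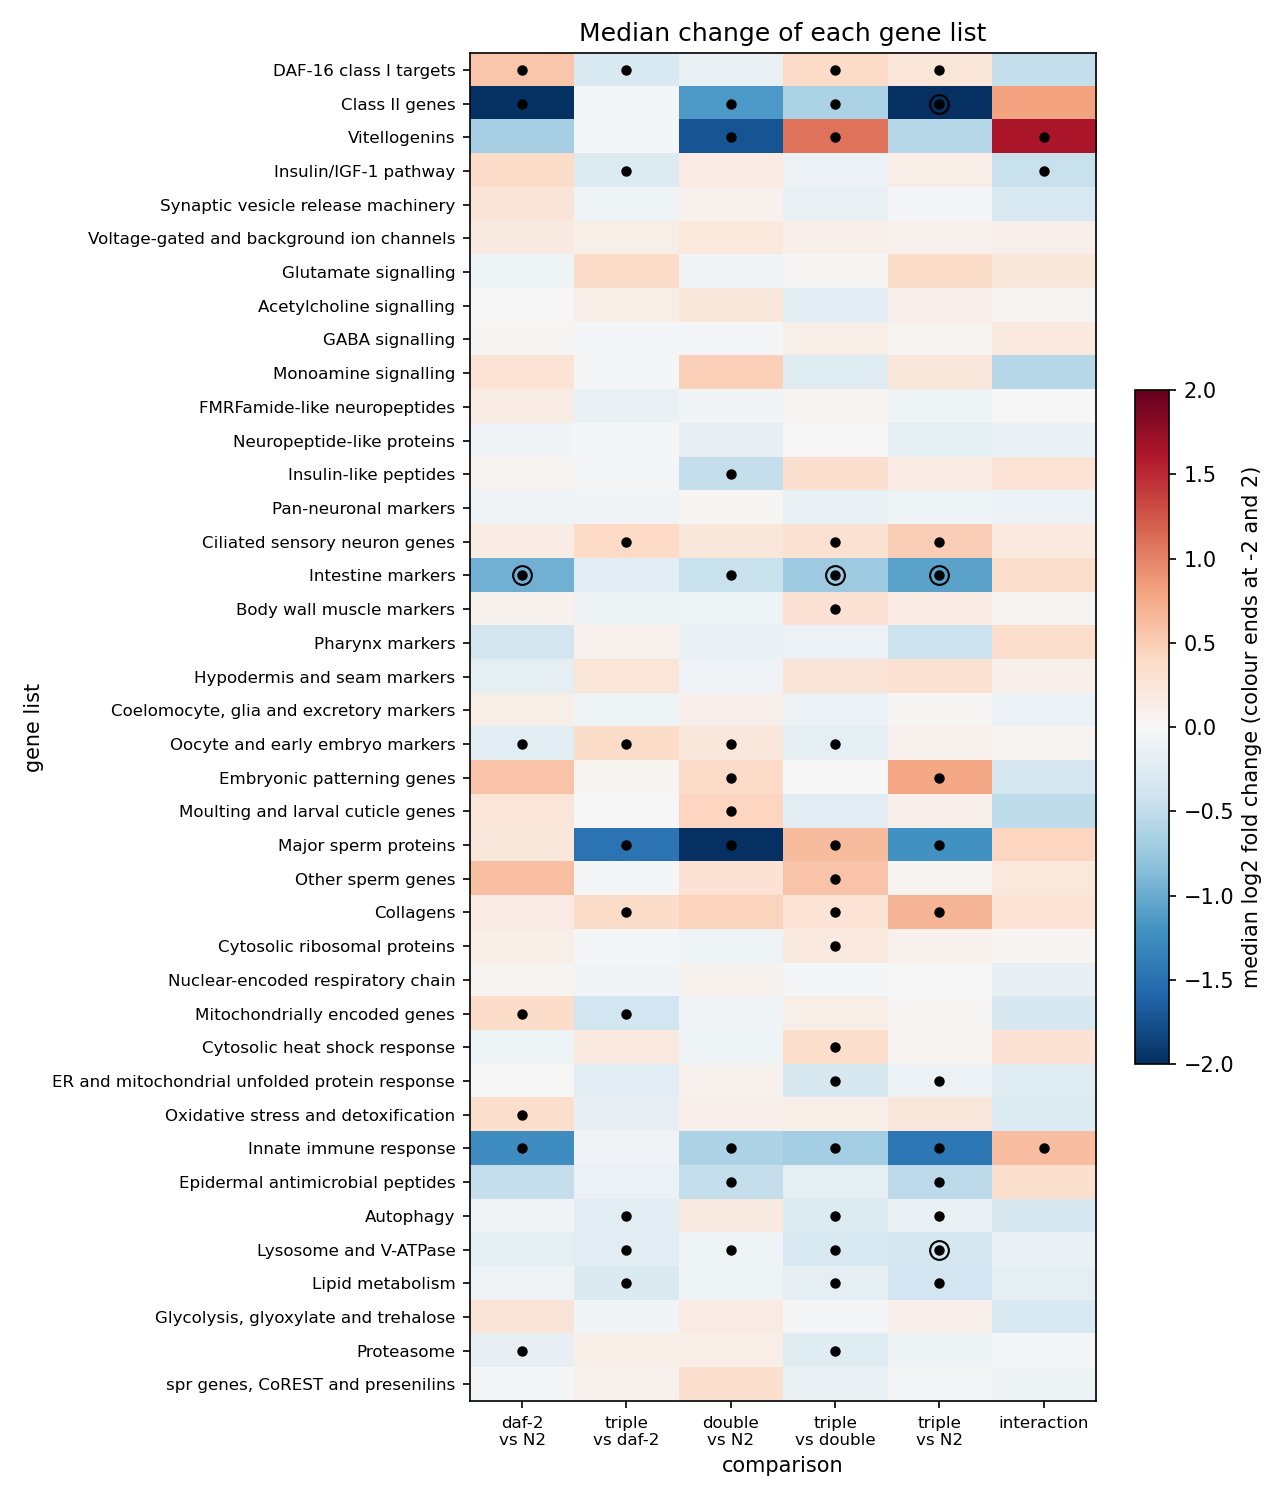
Colour gives the median log2 fold change of each of the 40 gene lists (vertical axis) in each comparison and the interaction (horizontal axis), with a dot where camera passed at the preset correlation and a ring where it also passed with an estimated correlation. Rings fall on intestine markers in 3 comparisons and on class II and lysosomal genes in the triple mutant against N2.

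For a set of genes the effect of losing spr-3 and spr-4 depended on daf-2. The interaction, the change in the triple mutant against daf-2 minus the change in the double mutant against N2, was positive for 897 genes and negative for 629 by edgeR (8.32% of those tested). The interaction was positive for the lists of yolk protein and innate immune genes and negative for that of the insulin/IGF-1 pathway. With an estimated correlation 0 of these 3 lists pass (camera adjusted p = 0.45 to 0.73). An example is fmo-2, a gene known to lengthen life when overexpressed, which fell with loss of spr-3 and spr-4 in N2 and rose in daf-2 (interaction 2.67 ± 0.19, edgeR adjusted p = 1e-06). Positive interactions were also found for ifas-1 (3.46 ± 0.36), lact-7 (3.74 ± 0.59), the dendrite anchoring gene dyf-7 (2.73 ± 0.39), the insulin genes ins-3 (2.13 ± 0.37), ins-4 (2.19 ± 0.41) and ins-5 (2.58 ± 0.43). They also met glt-3 (1.24 ± 0.23), the germ granule gene glh-2 (1.33 ± 0.24), rme-2 (1.55 ± 0.2), nos-2 (0.98 ± 0.19), the innexin gene inx-14 (1.17 ± 0.19) and the glycogen phosphorylase gene pygl-1 (1.39 ± 0.23). The lysozyme gene ilys-2 fell less in the daf-2 background (1.95 ± 0.32), and lys-3 fell in N2 and rose in daf-2 (2.68 ± 0.32). The gene F15H10.5 reached 19.2 ± 3.08 CPM only in the triple mutant. Negative values met the kinase genes akt-2 (-1.01 ± 0.18) and pdk-1 (-1.04 ± 0.23), ist-1 (-1.85 ± 0.36), the fatty acid genes fat-6 (-1.12 ± 0.2), elo-6 (-1.29 ± 0.21) and hacd-1 (-1.74 ± 0.34), lipl-4 (-1.21 ± 0.24) and the gluconeogenesis gene pck-1 (-1.29 ± 0.19). They also met the laminin gene lam-1 (-2.49 ± 0.37), dao-6 (-2.43 ± 0.41), nas-37 (-2.61 ± 0.44), flp-6 (-1.78 ± 0.3) and the immune gene irg-5 (-1.67 ± 0.34).

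Vitellogenins had a positive interaction as a list (1 up, 0 down of 6, 4 and 0 over the list alone, median 1.63, camera adjusted p = 5.3e-05, adjusted p = 0.45 with an estimated correlation). So had innate immune genes (8 up, 1 down of 39, 9 and 2 over the list alone, camera adjusted p = 0.004, adjusted p = 0.73 with an estimated correlation). The insulin/IGF-1 pathway was negative (0 up, 5 down of 18, 1 and 7 over the list alone, camera adjusted p = 0.016, adjusted p = 0.45 with an estimated correlation). It loses its call without replicate 2 of daf-2, 1 of the double or 2 of the triple mutant (camera adjusted p = 0.066, 0.063 and 0.051), and innate immunity without either of the latter 2 libraries (0.1 and 0.051). Vitellogenins and innate immunity are not called by fry (adjusted p = 0.095 and 0.19). Synaptic vesicle release (0 up, 4 down of 30), glutamate (1 and 1 of 28), acetylcholine (0 and 0 of 42), monoamine (0 and 0 of 27) and pan-neuronal genes (1 and 3 of 24) did not pass (camera adjusted p = 0.13, 0.55, 0.94, 0.18 and 0.69). The first passes without replicate 3 of the triple mutant (camera adjusted p = 0.038), and monoamine genes are negative by fry (adjusted p = 0.046). Removing replicate 2 of the double mutant raises the interaction to 2505 genes, removing replicate 3 of daf-2 lowers it to 772, and DESeq2 calls 2329.

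Across all 18342 tested genes the fold changes with loss of spr-3 and spr-4 correlated weakly between backgrounds. The fold changes correlate at 0.22 (Spearman 0.17), with 280 genes up in both (62.9 expected by chance), 227 down in both (80.5 expected) and 43 and 105 moved in opposite directions. Of the 2141 genes changed in the double mutant, 63.9% moved the same way in the daf-2 background, by a median of 0.22 against 0.86. The daf-2 effect was shared to a greater degree (correlation 0.37, Spearman 0.28, 519 up in both and 611 down in both where 123 and 160 are expected, 26 and 82 opposite). Of the 3772 genes it changed in N2, 73.8% moved the same way without spr-3 and spr-4, by a median of 0.35 against 0.96. These values compare pairs that have no library in common.

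Of the genes that daf-2 raised, 429 were lowered again by loss of spr-3 and spr-4 (117 expected), 511 that it lowered were raised (136 expected), and 51 and 96 moved further up or down. The correlation of both changes is -0.31 (Spearman -0.37), but the daf-2 libraries enter both with opposite sign, which alone makes such values negative. Data simulated with no difference between any of the genotypes, so that only the shared libraries act, gave a correlation of -0.52 (-0.54 to -0.49 over 20 draws) and 66.9% of genes with opposite signs, where 64.4% were observed. Real effects, which the simulation lacks, also enter the observed correlation and share of opposite signs. Setting these against the simulated values therefore decides neither for nor against a reversal. The covariance of -0.339 is more negative than the simulated -0.157 (-0.166 to -0.149). The simulation holds no real effects, so how many of the 429 and 511 genes owe their calls to noise in the shared daf-2 libraries was not tested. In the triple mutant against N2 sod-3, icmt-1 and alh-2 stayed high and lys-3, act-5 and dod-19 stayed low.

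**Figure D4:**
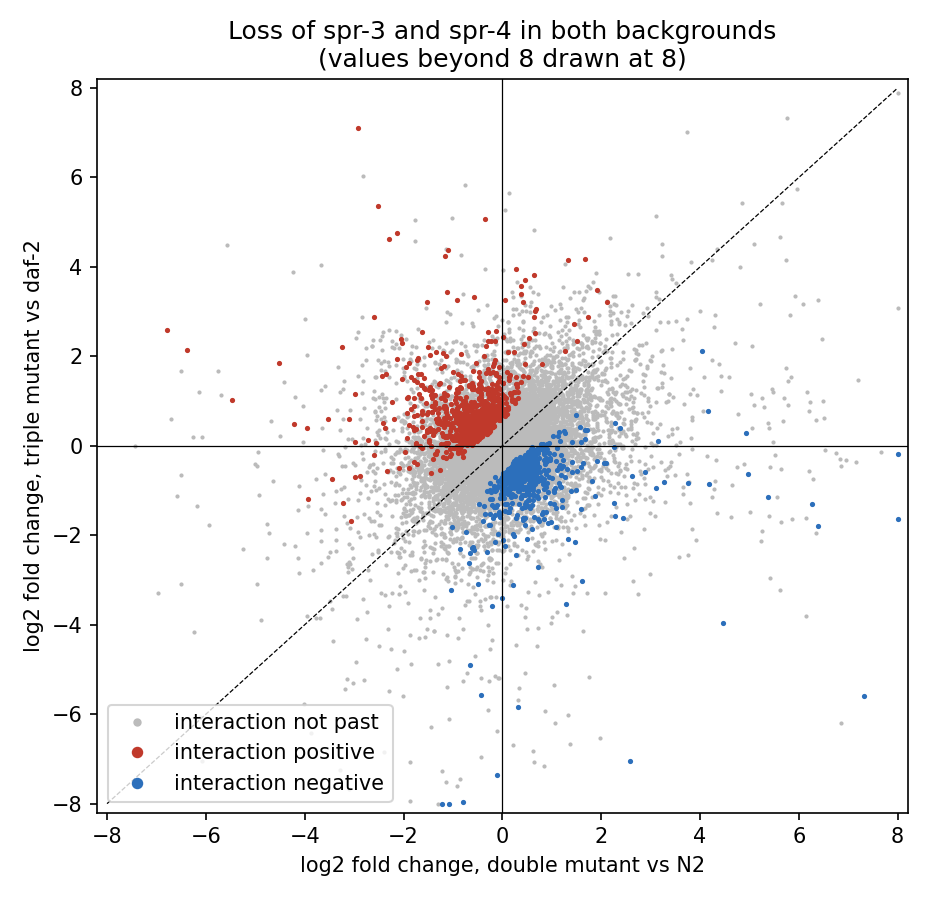
Each point is a tested gene, with its log2 fold change in the double mutant against N2 (horizontal axis) and in the triple mutant against daf-2 (vertical axis), and the dashed line marks equal change. The 897 genes with a positive interaction (red) lie above the line and the 629 with a negative one (blue) below it.

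The log2 fold changes of several families carry a limit from the reads. Transcripts of the vit, msp, nspc, ilys, cpr and W01B6 families are alike, and how reads that fit several places were counted is not given in the sources used here. The strand setting is not given either, so overlapping genes such as sod-3, mgl-1, nrx-1, osm-3, gcy-35 and ser-7 may hold reads of their neighbours. Without molecular tags the intervals from few reads cover counting error only. The median, mean and camera direction of a list differ in sign in 35 of the 240 list results, and 0 of these passed. Examples are insulin-like peptides in daf-2 against N2 (median 0.06, mean -0.37) and in the triple against the double mutant (median 0.32, mean -0.05). The genes named above were picked by hand from those the fixed rule gives, partly because their calls hold when a library is left out. Of all 804 calls the rule gives, 258 (32.1%) are lost without some library, so a call of edgeR for a gene not named here is less steady than the examples.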

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

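The interaction test was planned, and the comparison with other splits of the libraries and the grouping of the genes below were chosen after its result was seen. The effect of losing spr-3 and spr-4 differed between the N2 and daf-2 backgrounds for 1526 genes by edgeR. Of 100 drawn reassignments (200 possible) of the spr genotype within both backgrounds, 1 (the real one) gave as many genes. The highest other gave 800, but the others mix genotypes within groups, so chance is not excluded. Among the 141 named genes, which were picked by hand after their values were seen, 62 passed, 33 with a positive and 29 with a negative interaction, given below as log2 values. No test for single outlying libraries was made within the groups of 3. Counts of replicate 2 of the double mutant differ from those of replicates 1 and 3 by a chi-square per degree of freedom of 143 and 162, and replicates 1 and 3 from each other by 48.6. There are no deposited values outside the comparisons.

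As lists, vitellogenins (camera adjusted p = 5.3e-05) and innate immune genes (0.004) had a positive interaction and the insulin/IGF-1 pathway (0.016) a negative one, and none of these 3 passed with an estimated correlation (adjusted p = 0.45, 0.73 and 0.45). A positive value means that the log2 change with loss of spr-3 and spr-4 is higher in daf-2 worms than in N2, as a smaller fall, a larger rise or a rise in place of a fall. The groups below follow known functions and were not tested as groups. Intestinal and immune genes with such values are fmo-2 (2.67), lys-3 (2.68), ilys-2 (1.95), zip-10 (1.04), act-5 (1.03), ifb-2 (1.21), ifas-1 (3.46), dod-19 (1.16), cpr-5 (1.41) and lipl-8 (6.5, from few counts in the double mutant). Germline genes are rme-2 (1.55), nos-2 (0.98), mex-5 (0.82), puf-5 (0.77), glh-2 (1.33) and the gap junction gene inx-14 (1.17). The oocyte list did not pass (7 up, 1 down of 40, camera adjusted p = 0.13), and meiotic htp-1 is negative. Genes of cilia, neurons and peptides are dyf-7 (2.73), dyf-2 (1.48), arl-13 (1.52), glt-3 (1.24), nlp-56 (1.67), ins-3 (2.13), ins-4 (2.19) and ins-5 (2.58). Muscle, cuticle and other genes are unc-15 (1.18), act-4 (1.59), col-71 (1.26), col-81 (1.57), pygl-1 (1.39), lact-7 (3.74), icl-1 (1.33), hsp-16.41 (2.39) and F15H10.5 (4.56).

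Negative values, the reverse, were found in the insulin/IGF-1 pathway for akt-2 (-1.01), pdk-1 (-1.04), ist-1 (-1.85) and pqm-1 (-0.85). Metabolic genes are fat-6 (-1.12), elo-6 (-1.29), hacd-1 (-1.74), lipl-4 (-1.21) and pck-1 (-1.29), and genes of lysosomes and autophagy are cpl-1 (-0.73), vha-12 (-0.68), vha-3 (-0.99) and epg-2 (-1.88). Stress, immune and other genes are hsp-12.6 (-1.39), cyp-34A9 (-0.97), icmt-1 (-1.08), dao-6 (-2.43), col-50 (-1.73), fipr-23 (-1.99) and irg-5 (-1.67). Neural genes are unc-18 (-0.62), ric-4 (-1.09), egl-3 (-0.75), flp-6 (-1.78) and osm-3 (-1.53), and other genes are nas-37 (-2.61), lam-1 (-2.49) and htp-1 (-0.87). The fitted value of clx-1 (-9.64) rests on a genotype with 0 counts and is no bound. Since the interaction is the same number for both factors, these values also say how much the daf-2 effect differs with and without spr-3 and spr-4.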

How the results depend on the processing

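Among the alternatives, those without replicates 1 and 3 of the double mutant and with all libraries thinned to the smallest total were chosen only after the results were seen. No called value reversed where this was checked: genes named in the text and focal genes under DESeq2 size factors, DESeq2, the replicate block and each library left out (the former also under limma-voom), lists under DESeq2 size factors, estimated correlation, fry, the block and libraries left out, and correlations under DESeq2 size factors, the 10 CPM filter, the block and libraries left out. Single genes were not followed under the other alternatives. Here reversed means that a called value changed sign or was called with the opposite sign. Where a count changes, the cause was not tested, except that stricter thresholds call fewer genes by construction.

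With a log2 fold change of 1 or more the counts were 1812 (daf-2 against N2), 1080 (triple mutant against daf-2), 862 (double mutant against N2), 1157 (triple against double mutant), 2095 (triple mutant against N2) and 950 (interaction), and with an adjusted p under 0.01 they were 2118, 1082, 654, 1234, 2242 and 434. Limma-voom with quality weights called 3977 genes in the triple mutant against daf-2, among them 2421 of the 2461. DESeq2 called 2329 genes in the interaction, among them 1499 of the 1526. A fit of N2 and the double mutant only called 983. All other counts under other tools, scalings, filters and equal depth stayed within 1.5 times of the main count, and scalings moved the median of all genes by at most 0.036. Without replicates 1 and 3 of the double mutant, where the lone library left is assumed to vary like the other groups, the double mutant against N2 gave 277 genes (175 up, 102 down, 63.2% up against 43.4% with all libraries), the triple against the double mutant 790 (38.2% up against 47%) and the interaction 357 (63% up against 58.8%).

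Leaving out each library in turn gave 2600 to 4132 genes in daf-2 against N2 and 2931 to 4313 in the triple mutant against N2. The triple mutant against daf-2 gave 1376 to 2841, with 1568, 1376 and 1525 without replicates 2 and 3 of daf-2 and replicate 3 of the triple mutant. The double mutant against N2 gave 943 to 3139, with 1048 and 1011 without replicates 1 and 3 of N2, and 1030 and 943 without replicates 1 and 3 of the double mutant. The triple against the double mutant gave 1582 to 3303, with 1582 and 1693 without replicate 3 of the double and of the triple mutant. The interaction gave 772 to 2505, with 958 and 974 without replicates 1 and 3 of N2, 925 and 772 without replicates 2 and 3 of daf-2, 940, 2505 and 948 without replicates 1, 2 and 3 of the double mutant, and 923 without replicate 3 of the triple mutant.

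The number of gene lists called depends most on the correlation assumed between genes. With an estimated correlation 1, 0, 0, 1, 3 and 0 lists passed in the order above, where 8, 10, 11, 18, 13 and 3 passed with the preset value, and fry called 13 in daf-2 against N2. Leaving out a library gave 7 to 10, 9 to 11, 6 to 16, 15 to 19, 11 to 14 and 1 to 7 lists. For the double mutant against N2 it was 6 without replicate 3 of N2, and for the interaction 6 and 7 without replicates 2 and 3 of N2, 6 without replicate 1 of daf-2, 1 and 6 without replicates 1 and 2 of the double mutant, and 1 and 7 without replicates 2 and 3 of the triple mutant. Without replicates 1 and 3 of the double mutant 7 lists passed in the triple against the double mutant.

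The correlation of the spr effects in both backgrounds (0.22, jackknife standard error 0.046) was 0.16 with a filter of 10 CPM and 0.15 to 0.2 with a library left out. That of the daf-2 effects (0.37, standard error 0.063) was 0.55 with the filter and 0.29 to 0.36 with a library left out, and that of the daf-2 change against the spr change in daf-2 (-0.31, standard error 0.157) was -0.45 to -0.28.

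Single calls are less steady than the named genes make them look, since these were picked partly for holding when a library is left out. Of the 804 calls among the 1055 gene results given by the fixed rule, 258 (32.1%) are lost without some library, 110 results gain a call and 0 calls change sign. Of the 204 calls picked for the text outside the focal genes 1 is lost, that of hsp-16.41 in daf-2 against N2, and the 583 calls not named lose 249 (42.7%). The focal genes were not picked this way, and 8 of their 17 calls (47.1%) are lost. They are daf-16 and hop-1 in daf-2 against N2 (edgeR adjusted p up to 0.071 and 0.053), daf-2 and mtl-1 in the double mutant against N2 (up to 0.25 and 0.14), spr-3, hop-1 and mtl-1 in the triple against the double mutant (up to 0.081, 0.15 and 0.075) and spr-4 in the triple mutant against N2 (0.052 without replicate 2 of N2). For daf-2 this holds for each library but replicate 2 of the double and of the triple mutant, and for mtl-1 in the double mutant for each but replicate 3 of N2, replicate 2 of daf-2 and replicate 2 of the triple mutant. For hop-1 in the triple against the double mutant it holds for each but replicates 1 and 2 of daf-2, replicate 2 of the double and replicate 1 of the triple mutant. The other libraries that end a call are replicate 1 of N2 and 2 of daf-2 for daf-16 and replicates 2 and 3 of daf-2 for hop-1, and in the triple against the double mutant replicate 3 of both for spr-3, and replicate 3 of the double and 2 of the triple mutant for mtl-1. Another 9 focal results gain a call, among them spr-1 in the triple mutant against N2 (0.0076 without replicate 2 of N2) and spr-2 in the triple against the double mutant (0.028 without replicate 2 of the double mutant). With DESeq2 size factors daf-2 in the double mutant is lost (edgeR adjusted p = 0.068).

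A term for the replicate number (the replicate block) gave 3417, 2110, 1773, 2357, 3651 and 1151 genes, 7, 10, 11, 18, 12 and 4 lists and correlations of 0.21, 0.36 and -0.32, with 3 focal gene calls lost. The numbers do not pair the libraries: residuals of libraries with equal numbers correlate at -0.067 to 0.064, 0 of 18 pairs above 0.1, and 3 of 12 libraries fit best with their own number. The block therefore mostly costs degrees of freedom.

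Depth limits what low genes can show, since a count of 3 in the smallest library, replicate 2 of daf-2 with 11892808 counts, equals 0.252 CPM of its raw total. Simulated 1.5-fold changes were recovered in at most 7.46% of genes by edgeR, and by DESeq2 in 13.4% in daf-2 against N2, so small changes are mostly missed. The STAR version, annotation release, strand setting and handling of reads that fit several places are fixed by the authors and were not varied here.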

Other observations

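The split comparisons and all tests on the genes apart in a replicate of the double mutant and on the genes moved alike were chosen only after the results were seen, as were the somatic lists without collagens and the neighbours on opposite strands, while the 3 main tests on chromosome X were written before. The genes of this paragraph were looked up by name after the report was written, outside the rule for named genes, and all those looked up are given, without a test of leaving out libraries. The intestinal aquaglyceroporin gene aqp-1 was lower with the daf-2 mutation both with spr-3 and spr-4 (76 ± 36.8 to 10.9 ± 1.28 CPM, edgeR adjusted p = 2e-05) and without them (57.9 ± 15.3 to 8.44 ± 1.41 CPM, 5.3e-05), and did not pass with loss of spr-3 and spr-4. The sex determination gene fem-3 was lower in daf-2 than in N2 (-0.69 ± 0.13, edgeR adjusted p = 0.00094) and in the triple than in the double mutant (-0.76 ± 0.13, 0.00072). The G protein gene egl-30, which acts in neurons and muscle, fell in the double mutant against N2 (-0.94 ± 0.23, edgeR adjusted p = 0.018) and had a positive interaction (1.3 ± 0.33, 0.023). The synaptic gene unc-13 (0.66 ± 0.22, edgeR adjusted p = 0.047) and the heat shock factor gene hsf-1 (0.59 ± 0.18, 0.025) were higher in daf-2 than in N2, and unc-13 was also higher in the double mutant than in N2 (0.71 ± 0.22, 0.049) with a negative interaction (-1.1 ± 0.31, 0.041).

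By edgeR 0 of the other genes looked up passed in any comparison: the regulators skn-1, pha-4, hlh-30, daf-12, glp-1 and gld-1, and the genes daf-9, tph-1, lgc-55, daf-28 and ins-1. The last 5 have few reads. The adjusted p of daf-2 against N2 was 0.13 for skn-1, 0.36 for pha-4, 0.72 for hlh-30 and 0.29 for daf-12.

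For the 5 pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05: 1 split, the real one, gave as many genes each time (3772, 2461, 2141, 2739 and 4068), and the highest of the others gave 0.

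A set of 43 transcripts, from abundant ones such as ule-5 to low ones such as smex-1 (7.11 CPM in that library), was at least 4-fold higher in replicate 2 of the double mutant than in replicates 1 and 3. The CPM of ule-5 were 6220 in replicate 2, 313 in replicate 1 and 130 in replicate 3, against means of 13700 in N2, 1360 in daf-2 and 6960 in the triple mutant. RNA of N2 worms as the full source is argued against, since genes high in N2 alone reached a median 0.143 of the N2 excess where 0.491 was needed. So is RNA of triple mutant worms (0.0336, 0.529 needed). The needed values rest on genes chosen for a gap, so a part stays open. The digit in the library name stays open: replicate 3 shares it and stood at 0.043 of replicate 2, which tests nothing for genes so chosen. No factor of the design parts the replicates, so no biological explanation was tested and the source stays open.

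With loss of spr-3 and spr-4 fewer genes on chromosome X were called up and more down than on autosomes, 1.53% and 10.9% against 6.02% and 6.37% in the double mutant against N2 and 1.96% and 11.6% against 8.05% and 6.17% in the triple mutant against daf-2, but the daf-2 mutation tilts X the same way (7.59% and 13.7% against 10.4% and 11.2% in N2, 6.39% and 14.9% against 7.64% and 7.33% without spr-3 and spr-4), so the pattern is not shown to be particular to spr-3 and spr-4. Expression level and gene length are argued against, since autosomal genes matched for both had at least 5.58%, 7.8% and, in the triple mutant against N2, 13.6% called up in each of 100 matchings (3.07% on X there). A smaller somatic RNA share and a common shift of all X genes stay open. Within somatic lists X genes lay below autosomal genes (-0.36, -0.3 and -0.39, and -0.31, -0.23 and -0.28 without collagens, in the same order), but these pool tissues that moved differently. Over ribosomal protein, proteasome and respiratory chain lists, with 8 X genes, the difference was 0.03, -0.32 and -0.54. The rule for the shift first used only the triple mutant against N2, which spoke for it, and was then changed to need all 3 comparisons.

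Loss of spr-3 and spr-4 moved 507 genes the same way in both backgrounds. Variants carried along near the mutated genes are argued against as the source of most of them, since 9.66% lie within 2 Mb of spr-3 or spr-4 where 8.16% of tested genes do, but a small part stays open, as the interval reaches just past the bound of 1.5 times set for excluding any. Clusters of neighbouring genes are argued against as the source of most, since 23.9% (interval 20.2 to 27.8) have another within 20 kb. A part stays open here too, since the interval holds the bound of 25%. Neighbours are also more frequent than in 1000 permutations (121 genes, highest permuted 96, p = 0.001, the smallest they can give). The effect of losing spr-3 and spr-4 itself stays open as a hypothesis.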
